A study of Mus musculus with 18 samples.

How the data were processed

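RNA was measured in cultured mouse cells (C57BL/6) by 3' QuantSeq libraries read on an Ion Proton, per the labels' protocols. Per the labels, synovial fibroblasts (SF) came from the ankle and aortic valve interstitial cells (VIC) from mice of 8 weeks. The labels give 4 passages, 3 mice per genotype and libraries pooled 12 at a time. They do not say that each library comes from 1 mouse. SF WT replicate 3 read both Xist (102) and the Y-linked Ddx3y (67), and so, with less Ddx3y, did VIC WT replicate 2 (180 and 19) and SF TNF-DeltaARE replicate 1 (105 and 15). Ddx3y read 2 to 5 in the other libraries with Xist. The Y-linked Eif2s3y, Kdm5d and Uty read 16, 18 and 13 in SF WT replicate 3. They read 1, 1 and 4 in VIC WT replicate 2 and 0, 0 and 1 in SF TNF-DeltaARE replicate 1. Mixed samples are therefore not excluded for the libraries named here, above all for SF WT replicate 3. Per the submitters' processing notes the genome build was mm10 and DESeq was used. Aligner, read counter, annotation release, tool versions and the use of strand in counting are not given in the sources used here. Antisense and overlapping genes, and close copies of a gene, can therefore share reads.

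The data are 4 tables of the authors, which set each mutant genotype against wild type (WT) in each cell type, with 49548 genes each. The deposited expression values are a score: read counts that the authors normalized across libraries, per the file headers, and rounded to whole numbers. They are therefore neither raw counts nor CPM. The authors deposited a p-value and an FDR from DESeq for each of the 19253 genes they tested in these tables. The deposited log2 fold change is the authors' log2 of the mutant mean plus 1 over the WT mean plus 1, and its direction was checked on the values. The GC fraction of each gene is as the authors annotated it, per the file headers. Values were given for 17 of the 18 libraries in the labels, and SF of p75-deleted TNF-DeltaARE mice replicate 2 was not analysed here. Of the gene IDs, 49289 were found in GENCODE M21, 49281 of them on the same chromosome and strand, and coordinates in the report are those of the deposited tables (mm10).

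WT values were the same in both tables of a cell type (0 differed), and median-ratio factors over the 17 libraries lay between 0.993 and 1.01, so the tables shared the same normalization. Low values in each library took the steps of whole reads times 1 constant. That constant was estimated by likelihood from the low values, which gave 2750368 to 8921203 reads per library. On simulated libraries 16 of 17 constants were found within 0.005 and 1 was off by a factor of 2. For SF WT replicate 2 a constant lower by a factor of 2 was not excluded. Normalized totals ran from 4100146 to 5407884. Replicates of a group had log2 correlations of 0.940 to 0.976 and none looked like a copy of another, since 12.1% to 14.8% of values were identical in every pair. The number of reads per library bounds the precision of low genes, and reads without molecular identifiers are not independent molecules.

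Groups, replicate numbers, gene lists, the rule for named genes and a first set of alternatives were fixed from the labels before the data were examined. The plan named count tests and, for normalized values, limma within each deposited table. The second case applied. Values were taken as log2 of the value plus a pseudocount of 1, so that changes of low genes are understated. Genes tested by the authors with a mean of at least 10 were fitted with limma 3.58.1 (trend) in R 4.3.3, with genotype as the only term and no replicate block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. For contrasts across tables the plan gave values with no test. Tests of p75-deleted TNF-DeltaARE against TNF-DeltaARE (all libraries of the cell type) and of the cell types (all 17 libraries) were added after the data were seen, on the ground of the shared normalization. Their calls are to be read with that in mind.

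Gene lists, 33 in all and 7 of them markers of other cells, were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, where at least 3 members were measured. Each p was adjusted over the lists of a comparison. Calls adjusted over the list alone are given beside those over all genes. They are not corrected over lists or comparisons, and members of a list can move together. With the estimated correlation no list passed except contractile genes in VIC (p75-deleted against TNF-DeltaARE) and skeletal muscle genes between the cell types. No list that passed had a median, mean and test of differing sign.

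The rule named, per comparison, Tnf, Tnfrsf1b and Tnfrsf1a, and the 8 protein-coding genes with the largest increase and the 8 with the largest decrease among called genes. These had to reach an average log2 CPM of 3 with no overlap between groups, and predicted genes and pseudogenes were passed over. It added 4 members of each list that passed, by smallest p, and up to 3 called members of every other list. Of near-identical genes (values within a tolerance of 0.05, 127 genes in 44 clusters) only 1 was named among the largest changes. The list members printed were picked from the rule's genes after their values were seen. An item that met the rule is not reported here, and its values are left out of the sensitivity counts for named genes. Genes quoted from the authors' deposited table (Slc13a3, Isg15, Irf7), Lyz2, Acta1, the genes given for VIC WT replicate 2, Tspan18, Serpina3f and the remaining genes of the closing section were chosen after their values were seen.

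The tests were run on simulated data with 100 genes changed per fold size. Of 2-fold changes 16% were recovered in TNF-DeltaARE against WT SF, 10% in p75-deleted against WT SF and 4% in p75-deleted against TNF-DeltaARE SF, and of 4-fold changes 75%, 71% and 68%. In VIC, in the same order, 4%, 7% and 7% of 2-fold and 52%, 68% and 64% of 4-fold changes were recovered. Between WT cells of the 2 tissues these were 13% and 74%. For the difference of differences they were 2% and 24% (TNF-DeltaARE effect) and 1% and 22% (p75 effect), so most 2-fold changes were out of reach in every comparison. False calls numbered 1 to 8. Each gene was drawn independently in these simulations, unlike in real libraries that share structure. In TNF-DeltaARE against WT VIC, 4.56% of unchanged simulated genes had an unadjusted limma p under 0.05, and 2.49% of all real genes did. The rates may therefore not carry over to the real data. Overlaps between comparisons that share libraries were set beside 100 simulations of unchanged groups.

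Alternatives were no filter, a minimum of 5 CPM, pseudocounts of 0.1 and 10, an adjusted p of 0.01, a fold change of 2 on top, median-ratio rescaling, other sets of libraries in the fit, a replicate block and leaving out each library. Added after the data were seen were voom on the recovered reads, scaling to equal totals, a GC correction per library, 1 gene per near-identical cluster, and terms for sex transcripts or, in VIC, macrophage transcripts. Data were read with the data.table package (1.17.8), and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 estimated the reads and drew the plots.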

Results

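Mesenchymal cells from 2 tissues were profiled by 3' RNA sequencing (QuantSeq), which reads the 3' end of polyadenylated transcripts. Synovial fibroblasts (SF) are the connective-tissue cells of the joint lining and came from the ankle. Aortic valve interstitial cells (VIC) are the fibroblast-like cells of the heart valve. Both were cultured for 4 passages. The mice were wild type (WT), TNF-DeltaARE or p75-deleted TNF-DeltaARE (ColVIp75f/f-TNF-DeltaARE in the labels). TNF-DeltaARE mice lack the AU-rich element in the 3' untranslated region of Tnf that limits the life of its mRNA. In p75-deleted TNF-DeltaARE mice ColVI-Cre also deletes Tnfrsf1b, the gene of TNF receptor 2 (p75), in mesenchymal cells. The series asks what TNF receptor 2 of mesenchymal cells does in arthritis and in heart valve disease. The labels give 3 mice per genotype. Each cell type and genotype had 3 libraries, except 2 (replicates 1 and 3) for p75-deleted SF, whose replicate 2 was not analysed here. Estimated depth ran from 2750368 reads (SF TNF-DeltaARE replicate 1) to 8921203 (VIC WT replicate 1), and 18123 to 21772 genes per library lay above 0. Levels below are means ± SD of normalized counts, over n = 3 libraries or, for p75-deleted SF, n = 2. Changes are log2 differences of the value plus 1.

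Tnf, the cytokine gene carrying the TNF-DeltaARE deletion (chromosome 17, 35199381 to 35202007, minus strand of mm10), stood at 13 ± 10.4 in WT SF, 38.7 ± 2.89 in TNF-DeltaARE SF and 18.5 ± 4.95 in p75-deleted SF. In VIC it stood at 3 ± 4.36, 9.67 ± 14.2 and 93.3 ± 47.9 in that order. No contrast of Tnf between genotypes passed limma's test (TNF-DeltaARE against WT in SF 1.74, adjusted p = 0.173, and p75-deleted against WT in VIC 4.99, adjusted p = 0.43). For the latter the authors' deposited table lists a log2 fold change of 4.56 with an FDR of 0.000167. The p75-deleted VIC libraries also held more leukocyte transcripts, so which cells carried Tnf is open. Tnfrsf1b, the deleted receptor gene (chromosome 4, 145213463 to 145246870, minus strand), read 228, 433 and 230 in the WT SF libraries. It read 310, 413 and 261 in TNF-DeltaARE SF and 956 and 497 in p75-deleted SF. In VIC it read 98, 153 and 199 in WT, 255, 125 and 128 in TNF-DeltaARE and 121, 330 and 215 in p75-deleted libraries. Its values in p75-deleted cells were not below WT (SF 1.28, adjusted p = 0.0938, and VIC 0.51, adjusted p = 1). The labels do not give the deleted exons, and a 3' tag outside the deleted part is still read, so these values check neither the deletion nor the labels. Tnfrsf1a, the gene of TNF receptor 1, ranged from 313 ± 137 in TNF-DeltaARE VIC to 690 ± 276 in p75-deleted SF and passed in no contrast.

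Some cartilage and matrix transcripts fell in SF of TNF-DeltaARE mice (n = 3 against 3 WT). Comp, a cartilage and tendon matrix glycoprotein (chromosome 8, 70373558 to 70382066, plus strand), dropped from 1929.7 ± 379 to 185 ± 172 (-3.74 ± 0.50 SE, limma adjusted p = 0.0107). Cilp, another cartilage matrix protein, fell from 353 ± 81.6 to 61 ± 21.8. Sox9, the transcription factor of chondrocytes (551 ± 208 to 141 ± 52.3), and the matrilin Matn2 (145 ± 31.4 to 55 ± 5.20) fell as well. Of 10 cartilage genes 0 rose, 4 fell and 6 did not pass, or 0 and 7 adjusted over the list alone. Their median was -1.41 (camera adjusted p = 2.52e-08, adjusted p = 0.382 with an estimated correlation). The matrix list also moved down (median -0.27, adjusted p = 0.0036, adjusted p = 0.668 with an estimated correlation). Of its 40 members 1 fell over all genes, Col14a1 (230 ± 86.8 to 55.7 ± 26.1), while 1 rose and 7 fell adjusted over the list alone. Elastin, Eln (355 ± 265 and 31.3 ± 30.1, adjusted p = 0.054), and fibromodulin, Fmod (6611 ± 1388 and 2971 ± 281, adjusted p = 0.0541), did not pass over all genes. Among the largest decreases were the secreted proteins Egfl6 (-4.03), Smoc1 (-3.21), Ndnf (-3.08) and Clec3b, which is tetranectin (-3.19). Kng1, the kininogen gene, fell from 287 ± 28.5 to 41 ± 21.4. The glutathione-cleaving Ggt5 fell by 3.10 on the log2 scale. The lipid carrier Apoe (chromosome 7, 19696109 to 19699188, minus strand) fell from 386 ± 72.4 to 53 ± 16.8 (adjusted p = 0.00553).

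In the same comparison some inflammatory genes rose. The neutrophil chemokine Cxcl2 went from 84.7 ± 30.6 to 390 ± 168 (2.14, adjusted p = 0.0354). Ptges, the inducible prostaglandin E synthase, rose from 308 ± 26.9 to 624 ± 32.4 and the cytokine Tslp from 58 ± 11.1 to 254 ± 108. Of 44 TNF and NF-kB targets 2 rose, 0 fell and 42 did not pass, or 8 and 0 adjusted over the list alone. The list ranked higher as a group (adjusted p = 2.48e-06, adjusted p = 0.431 with an estimated correlation). Of 30 chemokines and cytokines 2 rose and 1 fell, or 8 and 2 adjusted over the list alone. That list also ranked higher (adjusted p = 1.22e-05, adjusted p = 0.431 with an estimated correlation). Its member that fell was Cxcl12, a stromal homing chemokine (23408 ± 9126 to 6780 ± 1305). The largest increase among the genes called by limma was that of Cck, the cholecystokinin gene (chromosome 9, 121489824 to 121495694, minus strand), from 20.7 ± 11.6 to 205 ± 56.0 (3.34). Enpp2, which encodes autotaxin, rose as well (156 ± 93.5 to 844 ± 213). U90926 (2.47), the arginine-synthesis enzyme Ass1 (1.81) and the tetraspanin Tspan11 (1.77) followed.

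Other lists moved as well. Synovial fibroblast markers fell as a group, with 0 up, 3 down and 18 not passing of 21, or 1 and 6 adjusted over the list alone (adjusted p = 0.031, adjusted p = 0.418 with an estimated correlation). Among them was Ly6c1, a surface antigen (803 ± 71.7 to 196 ± 60.3). Complement fell in 2 of 16 members, or 5 adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.668 with an estimated correlation). They were clusterin, Clu (816 ± 318 to 116 ± 20.7), and C4b (482 ± 98.7 to 114 ± 49.7). Wnt signalling ranked lower, with 1 of 26 called, Wnt16 (56.3 ± 12.5 to 15.3 ± 2.08), and 6 adjusted over the list alone (adjusted p = 0.000185, adjusted p = 0.324 with an estimated correlation). The 46 interferon-response genes ranked lower with 0 called, also adjusted over the list alone (median -0.51, adjusted p = 3.56e-05, adjusted p = 0.668 with an estimated correlation). The 41 DNA replication genes ranked higher with 0 called by either adjustment (median 0.52, adjusted p = 3.45e-07, adjusted p = 0.668 with an estimated correlation). The Nrf2 list ranked higher too, 4 up and 1 down adjusted over the list alone (adjusted p = 0.0237, adjusted p = 0.668 with an estimated correlation). From other lists, Tnfrsf11b, the decoy receptor osteoprotegerin (-1.94), and the growth factor Tgfb2 (-1.71) fell. Markers of other cells moved with this genotype. Skeletal muscle genes had a median of -1.20 (adjusted p = 1.57e-06, adjusted p = 0.431 with an estimated correlation), with 8 of 10 lower adjusted over the list alone. Skeletal actin, Acta1, stood at 250.3 ± 50.1 in WT and 151 ± 44.6 in TNF-DeltaARE. Cardiomyocyte genes (-0.88, adjusted p = 0.0151) and osteoclast, adipocyte and mural genes (-0.56, adjusted p = 0.0124) ranked lower, 1 and 2 of them falling adjusted over the list alone. With an estimated correlation these 2 lists had adjusted p = 0.537 and 0.417. The TNF ligand and receptor list (0.13, adjusted p = 0.324), TGF-beta and BMP signalling (-0.09, adjusted p = 0.262) and melanocyte and Schwann genes (0.31, adjusted p = 0.421) did not pass. In fits without 1 library the calls could end for the matrix (to adjusted p = 0.191), complement (0.266), DNA replication (0.217), Nrf2 (0.207), synovial marker (0.217), cardiomyocyte (0.135) and osteoclast, adipocyte and mural lists (0.104).

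In all, limma called 93 of 12051 genes between TNF-DeltaARE and WT SF, 21 up and 72 down. In 1987 genes (16.5%, chance 10%) the 2 groups did not overlap. The authors' deposited table holds 15 calls at an FDR of 0.05, of which 6 are among the 93. Voom called 47, 17 up and 30 down, and scaled to equal totals the split was 19 up and 43 down. The count hung on single libraries: without TNF-DeltaARE replicate 1, 2 or 3 it was 17, 16 or 196, and without WT replicate 1, 2 or 3 it was 24, 34 or 39.

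**Figure D1:**
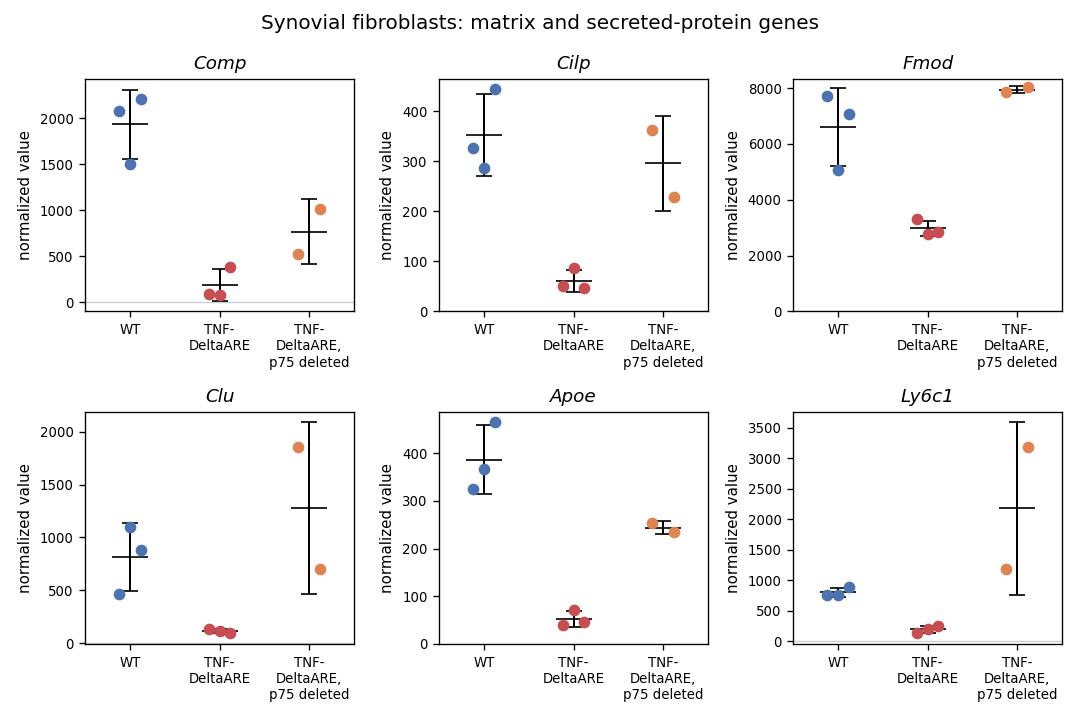
Normalized value (linear vertical axis) of 6 matrix and secreted-protein genes in SF, with 1 point per library for WT, TNF-DeltaARE and p75-deleted TNF-DeltaARE and black marks for the group mean ± SD. Comp lay at a mean of 1929.7 in WT, 185 in TNF-DeltaARE and 765 in p75-deleted TNF-DeltaARE SF, and the TNF-DeltaARE mean was the lowest in all 6 panels.

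SF of p75-deleted TNF-DeltaARE mice (n = 2) carried more of several stress and interferon-pathway transcripts than WT SF (n = 3). Nr4a1, an immediate early nuclear receptor (chromosome 15, 101266846 to 101274792, plus strand), rose from 119 ± 10.4 to 1727 ± 250.3 (3.84 ± 0.27 SE, limma adjusted p = 0.000336). The transcription factor Fos rose from 36.3 ± 5.51 to 120.5 ± 7.78. The eosinophil chemokine Ccl11 rose from 24 ± 10.4 to 182 ± 43.1 and the monocyte chemokine Ccl8 from 40.7 ± 20.3 to 278 ± 158, while the chemokine and cytokine list did not pass (adjusted p = 0.31), 2 up and 1 down of 30, or 2 and 2 adjusted over the list alone. Tmem176b, a membrane protein gene, rose from 2473 ± 566 to 19407 ± 9987, and Cck again stood higher (148 ± 62.9, 2.83). Tmem254a (2.80) and Tmem254c (2.88) also passed, but they belong to a family of similar neighbouring genes whose reads can be shared, so their values are uncertain. Of 46 interferon-response genes 4 rose, 0 fell and 42 did not pass, or 10 and 0 adjusted over the list alone (group adjusted p = 0.00721, adjusted p = 0.977 with an estimated correlation). They were the signalling factors Stat2 (160.3 ± 28.0 to 472 ± 12.0) and Irf9 (547 ± 139 to 1437 ± 284), Oasl2 (1.79) and the guanylate-binding Gbp2 (1.84). Among 27 Nrf2 genes the glutathione transferases Gstm1 (357 ± 16.5 to 2476 ± 989), Gstp1 (1.83) and Gstm2 (1.30) rose. In that list 0 fell, or 5 rose and 0 fell adjusted over the list alone (group adjusted p = 0.0415, adjusted p = 0.977 with an estimated correlation). Of 26 immediate early genes 2 rose by either adjustment (group adjusted p = 0.0415, adjusted p = 0.977 with an estimated correlation).

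Decreases were fewer. Marco, a macrophage scavenger receptor, fell from 284 ± 229 to 13 ± 14.1 (-4.39, limma adjusted p = 0.0274). The transcription factor Irx3 (-2.86), the matrix proteins Tgfbi (-2.55) and Fbn2 (-2.16) and the sulfotransferase Chst2 (-2.25) also fell. So did the adhesion protein Chl1 (284 ± 139 to 44.5 ± 2.12) and the glucocorticoid-responsive Fkbp5 (43.3 ± 11.6 to 8 ± 4.24). Hmgcs1, an enzyme of sterol synthesis, fell from 968 ± 380.3 to 232 ± 122. The cholesterol list moved down, 1 up and 1 down of 25, or 3 and 4 adjusted over the list alone (adjusted p = 0.0415, adjusted p = 0.977 with an estimated correlation). Its member that rose was Tm7sf2, a sterol reductase (1.98). The ribosomal list had a median of -0.31 (adjusted p = 0.0415, adjusted p = 0.977 with an estimated correlation), 1 up and 3 down of 43 adjusted over the list alone. Rps16 rose within it (1980.3 ± 420.0 to 6238 ± 142), and these genes have pseudogene copies that can share their reads. From other lists, Nfkb2 (1.70), the adhesion receptor Icam1 (1.77), the carbonic anhydrase Car9 (2.71) and the TGF-beta mediator Smad3 (1.42) rose. The fibroblast surface antigen Thy1 rose from 889 ± 74.8 to 2653 ± 772, and Il1rn, the interleukin-1 receptor antagonist, fell from 4087 ± 1288 to 1322 ± 621. Fabp4, a fatty-acid carrier of adipocytes, fell from 573 ± 179.8 to 200.5 ± 51.6. Its osteoclast, adipocyte and mural list moved down (median -1.14, adjusted p = 0.0415, adjusted p = 0.977 with an estimated correlation), 1 up and 2 down adjusted over the list alone. The class II antigen gene H2-Ab1 rose (16.7 ± 12.3 to 132 ± 57.3), while its macrophage and leukocyte list did not pass (adjusted p = 0.728). Each list that passed in this comparison lost its call without some single library, interferon (to adjusted p = 0.0914), immediate early (0.289), Nrf2 (0.317), cholesterol (0.497), ribosomal (0.615) and osteoclast, adipocyte and mural genes (0.497).

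Together 359 of 12051 genes passed, 322 up and 37 down, and 38.0% of genes did not overlap (chance 20% for 3 against 2). The authors' deposited table holds 6 calls (2 up, 4 down), with Nr4a1 at 3.84 and Slc13a3, a dicarboxylate transporter, at -4.86. Both p75-deleted libraries express Y-linked genes while WT replicates 2 and 3 express Xist, replicate 3 together with Y-linked genes. With a term for sex transcripts 2 genes passed. Voom called 186, and scaled to equal totals, which moved the median of all genes by -0.17, the split was 173 up and 59 down. Without p75-deleted replicate 1 the count was 35, and without WT replicate 1, 2 or 3 it was 32, 59 or 80.

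Against TNF-DeltaARE SF (n = 3), SF of p75-deleted TNF-DeltaARE mice (n = 2) had more transcript of some cartilage, interferon and class I antigen genes. Comp rose from 185 ± 172 to 765 ± 351 (2.35 ± 0.55 SE, limma adjusted p = 0.0247). Cilp rose from 61 ± 21.8 to 296 ± 94.8, fibromodulin from 2971 ± 281 to 7937 ± 119 and the joint lubricant Prg4 from 124 ± 11.5 to 438 ± 14.1. Of 10 cartilage genes 5 rose, 0 fell and 5 did not pass, or 6 and 0 adjusted over the list alone (group adjusted p = 0.00362, adjusted p = 0.797 with an estimated correlation). The procollagen C-proteinase enhancer Pcolce (1.61) and the collagen VI chains Col6a1 (380 ± 61.5 to 1626 ± 1069.8) and Col6a2 (1.91) rose. The matrix list as a whole did not pass (adjusted p = 0.0502). The Wnt antagonist Sfrp2 rose from 617 ± 809 to 3524 ± 1194 and clusterin from 116 ± 20.7 to 1278 ± 812. C4b rose from 114 ± 49.7 to 478 ± 101 and Ly6c1 from 196 ± 60.3 to 2180 ± 1413. Interferon-response genes rose in 16 of 46 cases and fell in 0, or 20 and 1 adjusted over the list alone. Their median was 1.08 (group adjusted p = 2.15e-07, adjusted p = 0.797 with an estimated correlation). Examples were Irf7, the interferon-inducible regulator (557 ± 244 to 2709 ± 788), Stat2 (2.11) and Oasl2 (2.24). Of 20 class I antigen genes 4 rose, or 10 adjusted over the list alone (group adjusted p = 0.0173, adjusted p = 0.797 with an estimated correlation). They included H2-K1 (1926 ± 896 to 8855 ± 6575) and B2m (3972 ± 1488 to 9852 ± 2088).

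The largest increases included the Eph receptor gene Ephb6 (chromosome 6, 41605482 to 41620509, plus strand), from 9.67 ± 0.577 to 114 ± 7.07, and the matrix protein gene Sned1, from 208 ± 119.8 to 1364 ± 145. Car9 (3.10), the growth factor Igf2 (2.98) and the splicing gene Scnm1 (2.85) rose too. Genes that fell included Fkbp5 (69 ± 7 to 8 ± 4.24, -3.04) and the cytochrome Cyp2e1 (220.3 ± 69.3 to 35 ± 11.3). The nephrin gene Nphs1 (-2.62), the exosome subunit gene Exosc2 (-2.18), the cystine transporter Slc7a11 (-2.22) and the matrix protease Mmp10 (-4.28) fell as well. Cxcl2 fell from 390 ± 168 to 68 ± 7.07 and Enpp2 from 844 ± 213 to 184 ± 69.3. Among 41 DNA replication genes 0 rose, and the replication factor Gins2 (275 ± 131 to 62.5 ± 9.19) and the proliferation antigen Mki67 (33.7 ± 23.7 to 5.50 ± 0.707) fell. Adjusted over the list alone 0 rose and 1 fell (group adjusted p = 0.0224, adjusted p = 0.896 with an estimated correlation). In cholesterol synthesis 5 of 25 fell, among them Fdps (-1.44), Hmgcs1 (-1.64) and Mvd (-1.28), and 1 rose. The counts were 7 and 2 adjusted over the list alone (group adjusted p = 0.00848, adjusted p = 0.896 with an estimated correlation). The immediate early genes Nr4a1 (2.84), Fos (2.20) and Klf2 (1.75) rose, as did the cell-cycle inhibitor Cdkn1a (2683 ± 542 to 10560 ± 4531). Notch3 (1.70) and the Notch coactivator Maml2 (1.28) rose, although the Notch list did not pass (adjusted p = 0.165). From oxidative phosphorylation, Cox4i1 rose (1.35) and Uqcrb fell (-1.08). That list, whose median (-0.03) and mean (0.02) differ in sign, did not pass (adjusted p = 0.774). Muscle markers moved with the cartilage and interferon genes. Myoglobin, Mb, rose from 17 ± 4.58 to 83.5 ± 27.6 in a cardiomyocyte list that passed (median 1.41, adjusted p = 0.0224, adjusted p = 0.797 with an estimated correlation), 3 up and 0 down adjusted over the list alone. Myl1, a skeletal myosin light chain, rose from 22 ± 9.17 to 84 ± 39.6, while the skeletal muscle list did not pass (adjusted p = 0.0772). Dropping a single library ended the call of the class I antigen (to adjusted p = 0.142), DNA replication (0.855), cholesterol (0.163) and cardiomyocyte lists (0.172).

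The test, which the plan did not include for values of this kind, called 1018 of 12051 genes, 740 up and 278 down. In 42.2% of genes the groups did not overlap (chance 20%). Scaled to equal totals, which moved the median of all genes by -0.20, the split turned to 449 up and 620 down, and voom gave 404 up and 362 down. Without TNF-DeltaARE replicate 1 or 2 the count was 356 or 431, without p75-deleted replicate 1 it was 420, and with only the libraries compared in the fit it was 663.

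**Figure D2:**
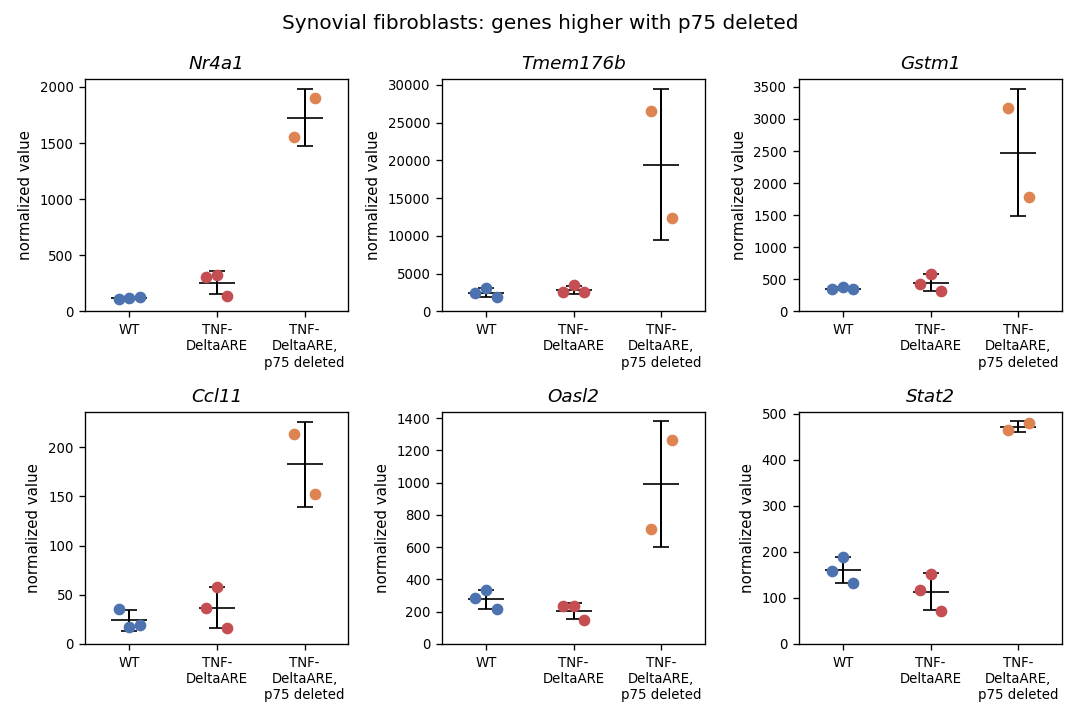
Normalized value (linear vertical axis) of 6 genes in SF, with 1 point per library for the 3 genotypes and black marks for the group mean ± SD. Nr4a1 lay at a mean of 119 in WT, 256 in TNF-DeltaARE and 1727 in p75-deleted TNF-DeltaARE SF.

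Of the 93 genes that differed between TNF-DeltaARE and WT SF, 43 were called in the opposite direction between p75-deleted and TNF-DeltaARE SF. These were 37 of the 72 that had fallen and 6 of the 21 that had risen, and 0 were called further from WT. Of the 43, 41 lay closer to WT than in TNF-DeltaARE, and 19 lay past WT, such as Ly6c1 (803 ± 71.7 in WT and 2180 ± 1413 in p75-deleted SF). Among those that had fallen were Comp, Cilp, Sox9, Col14a1, C4b, clusterin and Ly6c1. Clec3b (16 ± 12.5 and 94.5 ± 87.0), Kng1 (41 ± 21.4 and 222 ± 19.1) and Apoe (53 ± 16.8 and 244 ± 13.4) were others. Among those that had risen were Cxcl2, Enpp2 and Ass1 (355 ± 52.5 and 100 ± 7.07). The sign was opposite for 89 of the 93 (95.7%). In 100 simulations with no effect of the deletion the median was 72.6%, because both comparisons use the same TNF-DeltaARE libraries. Both mutant genotypes differed from WT in the same direction for 10 genes, 6 up and 4 down. Were the 2 sets of calls independent, 0.561 up and 0.221 down would be shared, a reference that ignores the shared WT libraries. In 100 simulations of unchanged groups the mean was 0 genes, but these hold no true changes to share and cannot gauge this overlap. The 10 genes included Cck, Chl1 and Cyp26b1 (4567 ± 274, 1552 ± 409 and 1893 ± 167). Ephb6 had fallen in TNF-DeltaARE and risen in p75-deleted SF (37.7 ± 3.79, 9.67 ± 0.577 and 114 ± 7.07). Over all genes the correlation of the 2 differences from WT was 0.281 in SF and 0.337 in VIC, against means of 0.399 and 0.417 in simulations with unchanged groups. Most simulations lay between -0.611 and 0.939 in SF and between -0.523 and 0.924 in VIC. The covariances were 0.118 and 0.0768, against 0.0807 (mostly -0.0745 to 0.341) and 0.116 (mostly -0.104 to 0.434). The real values lay within these wide ranges, so part of the overlap can come from the shared WT libraries. The 43 became 20 with voom, 11, 13 and 79 without TNF-DeltaARE replicate 1, 2 and 3, and 17, 15 and 16 without WT replicate 1, 2 and 3.

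No single gene passed between VIC of TNF-DeltaARE mice and WT VIC (n = 3 each), and some gene groups ranked lower or higher. Fibrillar collagen and matrix genes ranked lower (median -0.50 over 39 genes, limma camera adjusted p = 1.78e-06, adjusted p = 0.806 with an estimated correlation). Col12a1, a fibril-associated collagen, stood at 538 ± 136 in WT and 232 ± 93.2 in TNF-DeltaARE VIC, and Fmod at 661 ± 414 and 224 ± 121. Col11a1 stood at 302 ± 124 and 146 ± 26.5 and the proteoglycan Vcan at 96 ± 21.8 and 182 ± 38.0. Wnt signalling genes ranked lower (median -0.33 over 22, adjusted p = 0.0473, adjusted p = 0.836 with an estimated correlation), for example the Wnt antagonist Sfrp1 at 1208 ± 833 and 399.7 ± 66.1. Heat shock and unfolded-protein genes did too (median -0.13 over 28, adjusted p = 0.0473, adjusted p = 0.806 with an estimated correlation), for example Manf at 1425 ± 91.4 and 987 ± 202. Endothelial markers ranked higher in the same libraries (median 1.40 over 11, adjusted p = 0.00204, adjusted p = 0.806 with an estimated correlation), for example Esam at 14 ± 2.65 and 50 ± 28. In these 4 lists 0 genes were called, also adjusted over the list alone. The Wnt list did not pass without WT replicate 2 (adjusted p = 0.641), in which Sfrp1 read 2169 (764 and 691 in the others) and which also held SF transcripts such as Comp (72). The heat shock list did not pass in 4 of the 6 fits without 1 library (to adjusted p = 0.158 without WT replicate 1). The endothelial list did not pass in 1 of them, without WT replicate 1 (adjusted p = 0.0833). The macrophage list did not pass (median -0.95, adjusted p = 0.0522), its lysozyme Lyz2 reading 952, 38 and 36 in the 3 TNF-DeltaARE libraries. Limma called 0 of 11651 genes, 290 having an unadjusted p under 0.05, voom called 0, and 7.10% of genes did not overlap (chance 10%). The authors' deposited table holds 35 calls, 6 up and 29 down, and without TNF-DeltaARE replicate 1 limma called 3. Most of the 29, though not Rgs16 or Col2a1, were SF genes that WT replicate 2 held and the other VIC libraries nearly lacked. Abi3bp read 188 there and at most 8 in the others, Thbs4 162 and at most 25, and Hoxd13 44 and at most 1. Those decreases rest on that 1 WT library.

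VIC of p75-deleted TNF-DeltaARE mice (n = 3) carried more interferon-response and leukocyte transcripts than WT VIC (n = 3), as groups of genes. The 42 interferon-response genes had a median difference of 2.20 (limma camera adjusted p = 3.99e-47, adjusted p = 0.289 with an estimated correlation). Over all genes 0 were called, and 31 rose and 0 fell adjusted over the list alone, though they moved together (estimated correlation 0.76). Rsad2, the antiviral viperin (chromosome 12, 26442753 to 26456452, minus strand), stood at 26 ± 15.1 in WT and 587 ± 372 in p75-deleted VIC (4.34 ± 0.70 SE, adjusted p = 0.43). Ifit3 stood at 409 ± 139 and 1972 ± 1035, Ifit3b at 99.7 ± 27.3 and 892 ± 469, and the T-cell chemokine Cxcl10 at 7.33 ± 4.16 and 74 ± 49.8. Chemokines and cytokines ranked higher, with 6 of 24 up adjusted over the list alone (median 0.99, adjusted p = 4.45e-11, adjusted p = 0.289 with an estimated correlation). Ccl3 stood at 9.67 ± 11.6 and 91.7 ± 62.6, Il1b at 2 ± 2 and 37 ± 31.6, and the neutrophil chemokine Cxcl5 at 2626 ± 804 and 10289 ± 5449. NF-kB targets ranked higher (median 0.53, adjusted p = 1.25e-09, adjusted p = 0.345 with an estimated correlation), for example the adhesion receptor Vcam1 at 1544 ± 356 and 3551 ± 1673. Complement did too, 4 of 13 up adjusted over the list alone (median 1.01, adjusted p = 5.49e-09, adjusted p = 0.289 with an estimated correlation). Its factor B, Cfb, stood at 273 ± 167 and 1348 ± 593 and C3 at 917 ± 131 and 1892 ± 358. Class I antigen genes ranked higher (median 0.72, adjusted p = 4.45e-07, adjusted p = 0.345 with an estimated correlation), with the immunoproteasome subunit Psmb8 at 58.3 ± 56.3 and 171 ± 19.5. The contractile list ranked lower (median -0.58, adjusted p = 2.7e-06, adjusted p = 0.162 with an estimated correlation). Smooth muscle actin, Acta2, stood at 13184 ± 2057 and 6946 ± 3408 and calponin, Cnn1, at 396 ± 174 and 152 ± 75.8.

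Leukocyte markers moved with all of these groups. The macrophage and leukocyte list had a median of 2.32 (limma camera adjusted p = 5.7e-17, adjusted p = 0.345 with an estimated correlation). Its Cd52 stood at 204 ± 306 in WT and 1139 ± 387 in p75-deleted VIC and the complement component C1qb at 10 ± 16.5 and 78 ± 55.2. Endothelial markers ranked higher as well, 1 of 11 up adjusted over the list alone (median 0.80, adjusted p = 3.77e-05, adjusted p = 0.289 with an estimated correlation). Matrix proteases ranked higher (median 0.21, adjusted p = 0.0135, adjusted p = 0.345 with an estimated correlation), for example the neutrophil collagenase Mmp8 at 13.3 ± 4.04 and 68 ± 53.2. Hypoxia and glycolysis genes did too (median 0.37, adjusted p = 0.000705, adjusted p = 0.373 with an estimated correlation), with the glucose transporter Slc2a1 at 48 ± 13.5 and 102 ± 27.8. Position genes of the Hox list also ranked higher (median 0.42, adjusted p = 0.0297, adjusted p = 0.29 with an estimated correlation). The protease (to adjusted p = 0.272), hypoxia (0.113) and Hox calls (0.149) ended when 1 library was left out, the Hox call in 4 of 6 such fits. In the lists given here without such a count, 0 members passed adjusted over the list alone. Limma called 0 of 11651 genes, 459 having an unadjusted p under 0.05, voom called 0, and 7.84% of genes did not overlap (chance 10%). The authors' deposited table holds 51 calls, 29 up and 22 down, 43 of them among the genes tested with limma. It lists Rsad2 at 4.44, Ifit3b at 3.15, Isg15 at 2.85 and Irf7 at 2.30. Many of the 22 listed lower, such as Rspo2, Abi3bp and Hoxd13, were SF genes that WT replicate 2 held and the other VIC libraries nearly lacked. WT replicates 2 and 3 express Xist and the p75-deleted libraries Y-linked genes, and with a term for sex transcripts limma called 16. Without WT replicate 2 or 3 it called 12 or 2, and in a fit over all 17 libraries 8.

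**Figure D3:**
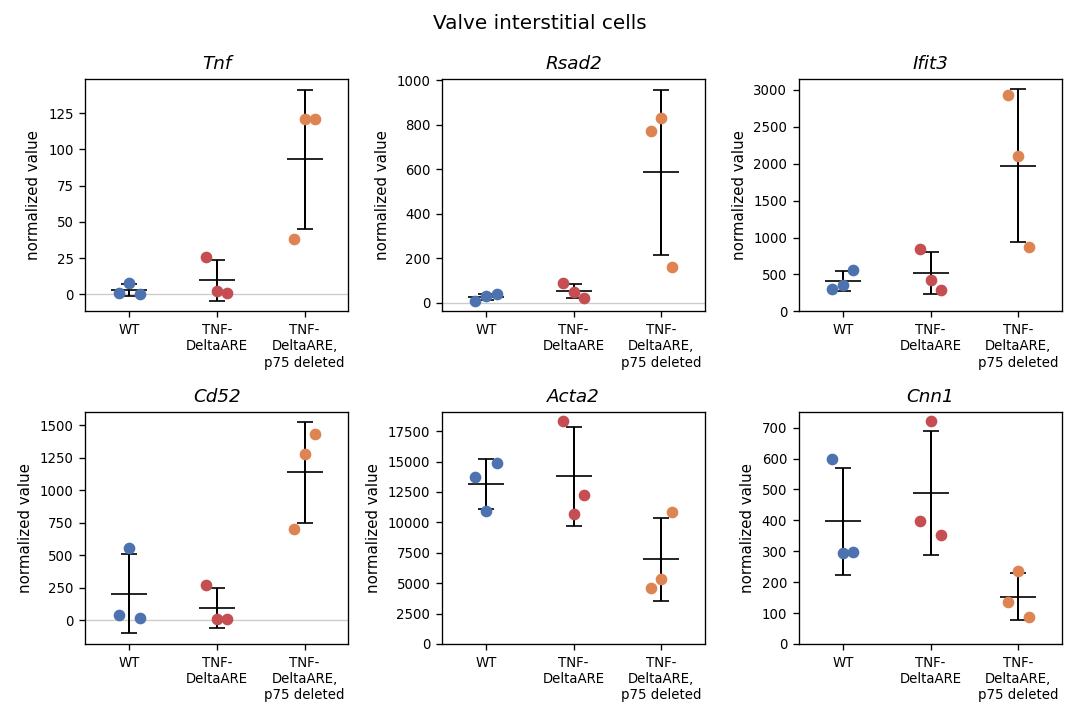
Normalized value (linear vertical axis) of 6 genes in VIC, with 1 point per library for the 3 genotypes and black marks for the group mean ± SD. Rsad2 lay at a mean of 26 in WT, 53.3 in TNF-DeltaARE and 587 in p75-deleted TNF-DeltaARE VIC, and Acta2 at 13184, 13781 and 6946, though no single gene passed the test.

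Compared with TNF-DeltaARE VIC (n = 3), p75-deleted VIC (n = 3) differed by contractile, interferon and matrix genes as groups. The contractile list was lower (median -0.59 over 22 genes, limma camera adjusted p = 2.73e-07) and passed also with an estimated correlation (adjusted p = 0.0274). In it 1 rose and 2 fell adjusted over the list alone. Calponin stood at 489 ± 201 in TNF-DeltaARE and 152 ± 75.8 in p75-deleted VIC (-1.72, adjusted p = 0.599), and Actg2, an enteric smooth muscle actin, at 123 ± 58.6 and 33.7 ± 18.3. Acta2 stood at 13781 ± 4059 and 6946 ± 3408 and the collagen-binding integrin Itga11 at 2.67 ± 2.08 and 20 ± 6.25. Interferon-response genes were higher, 7 of 42 adjusted over the list alone (median 1.79, adjusted p = 2.82e-27, adjusted p = 0.405 with an estimated correlation). Rsad2 stood at 53.3 ± 32.7 and 587 ± 372 and Gbp7 at 32.3 ± 11.5 and 129.7 ± 17.6. Matrix genes were higher (median 0.47, adjusted p = 9.11e-09, adjusted p = 0.405 with an estimated correlation). Examples were the fibrillar collagen Col3a1 at 1913 ± 1464 and 4804 ± 2118 and Fmod at 224 ± 121 and 774 ± 291. NF-kB targets (median 0.42, adjusted p = 5.67e-06), class I antigen genes (median 0.85, adjusted p = 1.8e-06) and complement (median 0.45, adjusted p = 0.00238) ranked higher. With an estimated correlation these had adjusted p = 0.509, 0.462 and 0.509. Chemokines ranked higher, 2 up adjusted over the list alone (median 0.75, adjusted p = 2.36e-06, adjusted p = 0.509 with an estimated correlation). Ccl3 stood at 7.67 ± 12.4 and 91.7 ± 62.6 and the acute-phase gene Saa3 at 1208 ± 1121 and 3006 ± 676. Hypoxia and glycolysis genes (median 0.37, adjusted p = 4.24e-05, adjusted p = 0.405 with an estimated correlation) and matrix proteases (median 0.34, adjusted p = 0.025, adjusted p = 0.509 with an estimated correlation) ranked higher. Cholesterol synthesis ranked lower (median -0.22, adjusted p = 0.0193, adjusted p = 0.517 with an estimated correlation). Protease (to adjusted p = 0.156) and cholesterol calls (0.615) depended on single libraries. Beside all of these, the macrophage list had a median of 3.40 (adjusted p = 1.1e-17, adjusted p = 0.405 with an estimated correlation), 13 of 22 up adjusted over the list alone. Its Cd52 stood at 93.7 ± 153 and 1139 ± 387 and Aif1 at 38 ± 62.4 and 385 ± 159.9. In the lists given without such a count 0 members passed adjusted over the list alone. Limma called 0 of 11651 genes, 618 having an unadjusted p under 0.05, voom called 0, and 8.53% of genes did not overlap (chance 10%). The authors' deposited tables hold no test of this contrast, and in a fit over all 17 libraries limma called 4.

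WT cells of the 2 tissues (n = 3 each) differed in position, heart and joint genes among many others. By list, interferon-response genes had the smallest camera p and skeletal muscle genes the largest median difference, both lower in VIC. Tbx20, a cardiac transcription factor (chromosome 9, 24718138 to 24774303, minus strand), stood at 3 ± 3 in SF and 1185 ± 144 in VIC (8.60 ± 0.56 SE, limma adjusted p = 5.59e-08). Gata6, another heart factor, stood at 4.33 ± 1.15 and 68.3 ± 39.6. Tcf21 (132 ± 77.3 in VIC) was listed at 0 in every WT SF library. Of 18 heart and valve genes 9 were higher in VIC, 4 lower and 5 did not pass, or 9 and 7 adjusted over the list alone (group adjusted p = 0.0207, adjusted p = 0.141 with an estimated correlation). Limb position genes went the other way. Hoxa9 stood at 147 ± 28.6 in SF and 7 ± 9.54 in VIC, and the hindlimb factor Tbx4 at 53 ± 16.1 and 5.67 ± 1.53. In that list 2 were higher in VIC and 13 lower of 19, or 2 and 14 adjusted over the list alone (group adjusted p = 4.45e-07, adjusted p = 0.141 with an estimated correlation). Comp stood at 1929.7 ± 379 in SF and 31.3 ± 35.2 in VIC. VIC WT replicate 2 held more of such SF genes than the other VIC libraries, with Hoxa9 at 18, Hoxa10 at 24 and Comp at 72. The largest values toward VIC were also those of Upk3b, a mesothelial uroplakin (8.60), Serpinb9b (6.90), the microtubule protein Map2 (6.38) and the reticulon Rtn1 (6.10). Crct1 (8.33 ± 4.73 and 1652 ± 317), the muscle stress gene Ankrd1 (77 ± 43.9 and 9115 ± 3627) and the palmitoyltransferase Zdhhc2 (32.7 ± 6.11 and 2378 ± 718) were others. Toward SF they were those of the proton pump Atp12a (-7.03), granzyme E, Gzme (-6.89), Abi3bp (-6.66), Igf2 (-6.34) and Sned1 (-6.13). Stanniocalcin 1, Stc1 (1422 ± 557 and 18.7 ± 9.50), and thrombospondin 4, Thbs4 (2528 ± 718 and 66.7 ± 82.8), belonged to them too.

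Inflammatory and matrix lists were lower in VIC. Interferon-response genes were lower in 31 of 45 cases, or 38 adjusted over the list alone (median -2.47, limma camera adjusted p = 1.7e-15, adjusted p = 0.184 with an estimated correlation). Complement was lower in 10 of 16, or 11 adjusted over the list alone (adjusted p = 3.76e-07, adjusted p = 0.141 with an estimated correlation). Chemokines were lower in 11 of 27, or 18 adjusted over the list alone (adjusted p = 1e-07, adjusted p = 0.141 with an estimated correlation). Saa3 stood at 48156 ± 11214 in SF and 1261 ± 808 in VIC and Cfb at 16127 ± 7008 and 273 ± 167. Cxcl12 stood at 23408 ± 9126 and 1119 ± 278 and the stromelysin Mmp3 at 9705 ± 1237 and 515 ± 389. NF-kB targets followed, 1 higher and 11 lower of 44, or 1 and 13 adjusted over the list alone (adjusted p = 0.00103, adjusted p = 0.359 with an estimated correlation). So did class I antigen genes, 7 lower of 20, or 16 adjusted over the list alone (adjusted p = 1.35e-05, adjusted p = 0.17 with an estimated correlation). Proteases were 1 higher and 11 lower, or 1 and 16 adjusted over the list alone (adjusted p = 1.35e-05, adjusted p = 0.141 with an estimated correlation). Matrix genes were 2 higher and 20 lower of 40, or 3 and 23 adjusted over the list alone (adjusted p = 1.96e-07, adjusted p = 0.141 with an estimated correlation). Cartilage genes were 1 higher and 6 lower of 12, or 1 and 7 adjusted over the list alone (adjusted p = 0.000343, adjusted p = 0.141 with an estimated correlation). Bone genes were lower in 8 of 15, or 11 adjusted over the list alone (adjusted p = 2.04e-05, adjusted p = 0.101 with an estimated correlation). Wnt genes were 1 higher and 11 lower of 25, or 2 and 14 adjusted over the list alone (adjusted p = 4.11e-05, adjusted p = 0.141 with an estimated correlation). Among these genes were the calcification inhibitor Mgp (7082 ± 1176 and 966 ± 498) and the collagen gene Col1a1 (15736 ± 3144 and 4882 ± 1367). Synovial fibroblast markers were 3 higher and 12 lower of 21, or 4 and 13 adjusted over the list alone (adjusted p = 7.21e-06, adjusted p = 0.133 with an estimated correlation). Hypoxia genes were lower in 17 of 32, or 21 adjusted over the list alone (adjusted p = 1.61e-10, adjusted p = 0.13 with an estimated correlation). Cholesterol genes were lower in 5 of 25, or 6 adjusted over the list alone (adjusted p = 0.00373, adjusted p = 0.305 with an estimated correlation).

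Higher in VIC was the p53 and senescence list, 9 of 27 higher and 1 lower, or 11 and 3 adjusted over the list alone (limma camera adjusted p = 0.00176, adjusted p = 0.141 with an estimated correlation). Its member Perp stood at 5.33 ± 3.79 and 120.3 ± 37.0. DNA replication genes ranked higher with 0 called by either adjustment (adjusted p = 0.0238, adjusted p = 0.678 with an estimated correlation, and adjusted p = 0.333 without VIC WT replicate 1). Markers of other cells differed as well. The 8 skeletal muscle genes had a median of -4.28 (adjusted p = 1.39e-10, adjusted p = 0.0254 with an estimated correlation), 8 lower adjusted over the list alone. The osteoclast, adipocyte and mural list had a median of -2.03 (adjusted p = 0.0201, adjusted p = 0.141 with an estimated correlation), 3 lower adjusted over the list alone. The epithelial list did not pass, 1 higher of 3 (median 0.78, adjusted p = 0.222). In all 1801 of 12026 genes passed, 758 higher and 1043 lower in VIC, with 32.0% not overlapping (chance 10%). Scaled to equal totals, which moved the median by -0.17, the split was 536 and 1270.

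Whether TNF-DeltaARE acted differently in the 2 cell types was tested as a difference of differences. It was more positive in VIC for Apoe (3.70 ± 0.57 SE, limma adjusted p = 0.0203), which fell in SF and stood at 286 ± 58.1 in WT and 552 ± 260.2 in TNF-DeltaARE VIC. The retinoic acid hydroxylase Cyp26b1 followed (2.21), at 4567 ± 274 and 1552 ± 409 in SF and 787 ± 41.7 and 1228 ± 223 in VIC. Among 12026 genes 4 passed, all with a positive difference (VIC minus SF), and 495 had an unadjusted p under 0.05. The other 2, named after their values were seen, were Tspan18 (4.59) and Serpina3f (5.25), both low in VIC and below the filter there. Tspan18 read 78, 32 and 78 in WT and 7, 4 and 8 in TNF-DeltaARE SF, and 5, 4 and 4 and then 19, 13 and 12 in VIC. Serpina3f, not called in SF (adjusted p = 0.12), read 37, 112 and 51 and then 4, 13 and 22 in SF, and 0, 1 and 1 and then 14, 14 and 6 in VIC. Clusterin missed the threshold (3.99, adjusted p = 0.0815). As groups, endothelial (1.28, adjusted p = 0.0332), cartilage (0.94, adjusted p = 0.00852) and interferon genes (0.90, adjusted p = 7.54e-05) had the more positive effect in VIC. Complement (0.14, adjusted p = 0.00787), synovial markers (0.35, adjusted p = 0.031) and bone genes (0.13, adjusted p = 0.0235) did too. With an estimated correlation these 6 lists had adjusted p = 0.505 to 0.712. Macrophage (-1.21, adjusted p = 0.0332), chemokine (-0.48, adjusted p = 0.0332) and DNA replication genes (-0.43, adjusted p = 0.00244) had the more negative effect in VIC. Nrf2 (-0.42, adjusted p = 0.0332) and NF-kB genes (-0.21, adjusted p = 0.0332) went the same way. The estimated correlation gave these 5 adjusted p = 0.506 to 0.724. Adjusted over the list alone, 4 complement, 2 cartilage, 1 bone and 1 synovial marker genes had the more positive effect in VIC and 0 genes of the other lists passed. All of these lists lost their call in some fit without 1 library (to adjusted p = 0.116 for cartilage and up to 0.871 for DNA replication). For skeletal muscle genes, of which 2 passed the filter in VIC, the difference would mostly restate the change in SF and is not given, here or for p75 deletion. The 4 calls were not firm, since voom called 0. Without any 1 of SF TNF-DeltaARE replicates 1 and 2, SF WT replicates 1 and 3, VIC TNF-DeltaARE replicates 2 and 3 or VIC WT replicate 2 the count was 0, and without SF WT replicate 2 it was 1.

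The effect of p75 deletion on TNF-DeltaARE cells differed between VIC and SF for 21 of 12026 genes, 2 more positive and 19 more negative in VIC. Fkbp5 had the more positive effect in VIC (3.19 ± 0.49 SE, limma adjusted p = 0.0212), at 69 ± 7 and 8 ± 4.24 in SF and 44.7 ± 5.03 and 49.7 ± 2.89 in VIC. Ly6c1 (-5.22) and clusterin (-4.07) had the more negative one, standing in VIC at 14 ± 5.57 and 3 ± 1 and at 222 ± 141 and 117 ± 34.0. Prg4 (-3.45) stood in VIC at 16 ± 2.65 and 5 ± 3 and Apoe (-3.42) at 552 ± 260.2 and 243 ± 143. More negative too were the stress cytokine Gdf15 (-3.33), the linker histone Hist1h1c (-3.10), the matricellular Tinagl1 (-2.45) and the glutathione transferase Gsta4 (-4.93). Rps26 (-2.66) is a ribosomal gene whose pseudogene copies can share its reads. As groups, macrophage (3.37, adjusted p = 1.15e-06), chemokine (1.04, adjusted p = 0.0065) and interferon genes (0.65, adjusted p = 0.0188) had the more positive effect in VIC. NF-kB (0.57, adjusted p = 0.0065) and ribosomal genes (0.32, adjusted p = 0.0233) did as well. Contractile genes (-0.59, adjusted p = 0.0233) had the more negative one. Over these 6 lists the estimated correlation gave adjusted p = 0.703 to 0.857. Adjusted over the list alone, 7 chemokine and 3 ribosomal genes had the more positive effect in VIC, 2 chemokine and 2 ribosomal genes the more negative one, and 0 of the other lists passed. Without some single library the call ended for the NF-kB and chemokine (to adjusted p = 0.113 each), contractile (0.112), interferon (0.852) and ribosomal lists (0.51). Tnf did not pass (4.98, adjusted p = 0.114). Unadjusted, 1563 genes had a p under 0.05, voom called 1 gene, and scaling to equal totals, which moved the median by 0.20, left 4. The count was 0 without SF TNF-DeltaARE replicate 1, VIC TNF-DeltaARE replicate 2 or VIC p75-deleted replicate 1 or 2, 7 and 3 without SF TNF-DeltaARE replicates 2 and 3, and 2 and 149 without SF p75-deleted replicates 1 and 3. It was 3 without any 1 of the SF WT replicates, 68 and 4 without VIC TNF-DeltaARE replicates 1 and 3, and 4 without VIC WT replicate 2.

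**Figure D4:**
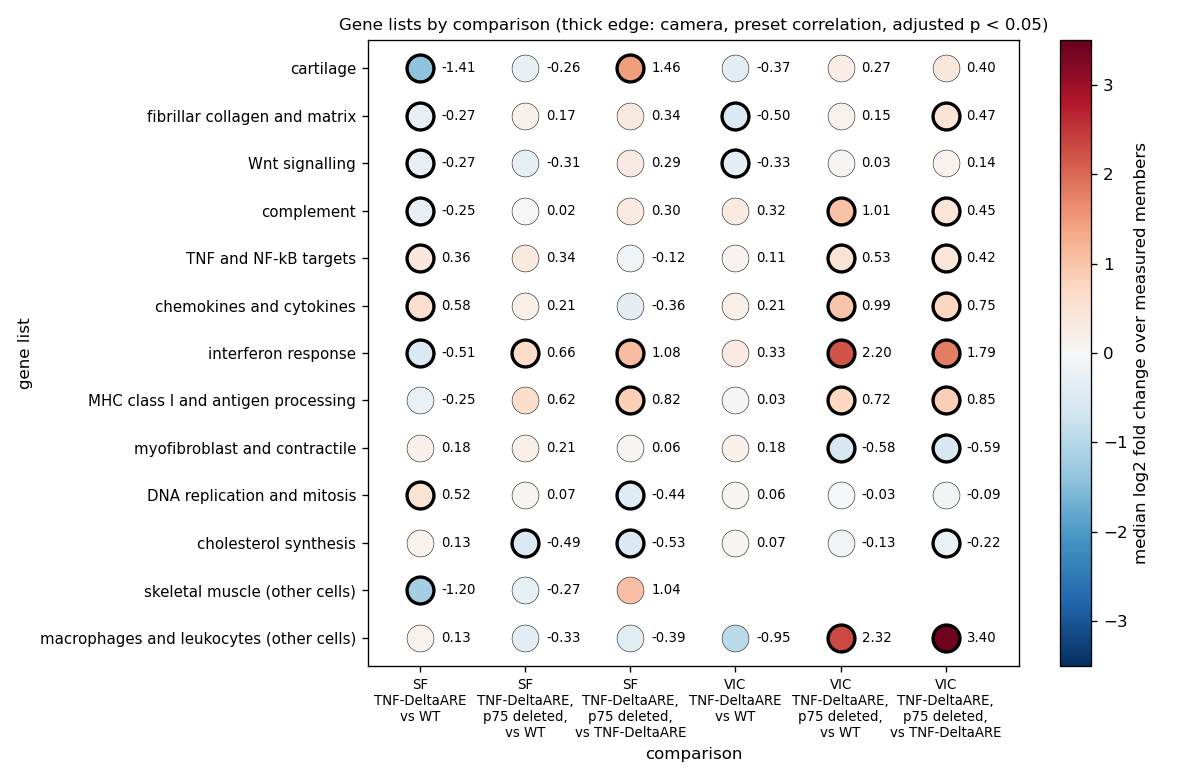
Median log2 fold change of 13 gene lists (vertical axis) in the 6 genotype contrasts (horizontal axis), printed beside each circle and shown by its colour, with a thick edge where camera with the preset correlation gave an adjusted p under 0.05 and no circle where fewer than 3 members were measured. The interferon list lay at -0.51 in TNF-DeltaARE SF, 0.66 in p75-deleted SF and 2.20 in p75-deleted VIC, each against WT.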

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

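The tests of chondrocyte RNA, of GC content, of shared TNF-DeltaARE libraries, of carry-over and of a mislabelled sample were chosen only after the result was seen, as was the use of a test across tables.

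The effect of TNF-DeltaARE differed between VIC and SF, by a test of the difference itself, for 4 genes. The log2 difference (VIC minus SF) was 3.70 for Apoe, 4.59 for Tspan18, 2.21 for Cyp26b1 and 5.25 for Serpina3f, with Tspan18 and Serpina3f below the filter in VIC. The p75 effect differed for 21 genes, with chance not excluded for either count. The difference was positive for Fkbp5 (3.19) and the pseudogene Hmgb1-ps7 (3.59). It was negative for the secreted or surface proteins Ly6c1 (-5.22), Apoe (-3.42), Prg4 (-3.45), clusterin, Clu (-4.07), Gdf15 (-3.33), Tinagl1 (-2.45) and Lrrc32 (-2.19). Negative too were the tetraspanins Cd151 (-1.92) and Cd81 (-1.82), the scavenger receptor Scara3 (-2.14) and the lysosomal fucosidase Fuca1 (-2.16). Others were Gsta4 (-4.93), Hist1h1c (-3.10), Rps26 (-2.66), Gtpbp1 (-2.01), Fkbp9 (-1.71), Rbfa (-1.87), talin, Tln1 (-1.66), and Bex3 (-1.77).

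In p75-deleted VIC each of the 42 interferon-response genes lay above WT (median 2.20), which was set against macrophage RNA and the sex of the mice as explanations. The tables argue against sex, since with a term for sex transcripts the median was 2.91 (2.06 without VIC WT replicate 1 to 3.39 without VIC TNF-DeltaARE replicate 2). Macrophage RNA in the cultures stays open: with a term for macrophage transcripts the median was 1.75, and the share kept ran from 49.3% (1.02, without VIC WT replicate 2) to 99.1% (2.23, without VIC WT replicate 3). The most abundant genes of that list were Lyz2 (629 ± 856 in WT, 1401 ± 751 in p75-deleted VIC) and Cd52 (204 ± 306, 1139 ± 387), 22 of its genes were measured in VIC, Ctss is also on the protease list, and the labels name no sort that would remove leukocytes. The deletion itself stays among the open explanations, untested.

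Cartilage genes were lower in TNF-DeltaARE than in WT SF (median -1.41, 4 of 10 called), set against chondrocyte RNA, GC content and sex. Against chondrocytes that still express their structural genes in the WT cultures, 7 of these genes together fell by 78 ± 51.5 (SE). This is 4.47% of the fall of Comp (1744 ± 241), and the most abundant of the 7, Col2a1, read 85, 32 and 162 in WT SF. Chondrocyte-derived cells without these transcripts after 4 passages would escape this test, so it does not speak against them. Against GC content, 4 of the 4 called genes passed after a GC correction. Against sex, the median with a term for sex transcripts was -1.47 (-1.62 without SF WT replicate 2 to -1.21 without SF WT replicate 3). An effect of the TNF-DeltaARE genotype is a candidate explanation, though skeletal muscle genes were lower too (median -1.20) and another mix of joint cells was not tested.

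The library labelled VIC WT replicate 2 held limb-position transcripts that the other VIC libraries nearly lacked, with Hoxd13 at 44, Hoxd11 at 34, Hoxa10 at 24 and Hoxa9 at 18, or 13.6% to 38.0% of the SF mean over 7 genes, of which 6 were higher there than in each other VIC library (Hoxa11 read 22 there and 41 in another). A mislabelled SF sample is argued against by 8 heart and valve genes, whose median there was 84.9% of the other VIC libraries (55.0% to 108%). Carry-over from the SF libraries is not settled. A first test was undecided, with 76.1% of 67 other SF genes within 3-fold of the limb genes' median share (20.4%). A test chosen after that took each of the 8 SF libraries as the source. For 7 of them, 6 to 8 of the 10 most abundant other SF genes lay below the limb genes' lowest share. Saa3 (2.96% of the SF mean) and Stc1 (1.41%) were among them. For SF TNF-DeltaARE replicate 3, 2 of the 10 did. No biological explanation was tested.

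Of the 93 genes called between TNF-DeltaARE and WT SF, 43 were called in the opposite direction between p75-deleted and TNF-DeltaARE SF. In 2 of 100 simulations that share the TNF-DeltaARE libraries but hold no effect of the deletion as many were (highest 1607). The simulations called a median of 300 genes between TNF-DeltaARE and WT, not 93. As a share of the genes called, 0 reached the real 46.2%. With so many more calls they cannot gauge how far chance differences fall back. They weigh only the shared libraries, not what else sets the p75-deleted ones apart.

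For 7 comparisons the libraries can be split in only 10 ways, which is too few for a share under 0.05. In SF the real count and the highest of the other splits were 93 and 1 (TNF-DeltaARE against WT), 359 and 0 (p75-deleted against WT) and 1018 and 4 (p75-deleted against TNF-DeltaARE). As many genes as in the real split were called in 1 of 10 splits each time. Between WT cells of the 2 tissues they were 1801 and 0, again 1 of 10. In VIC the real count was 0 in all 3 genotype comparisons, so 10 of 10 splits gave as many. The highest other count was 806 for TNF-DeltaARE against WT, in the split that puts VIC TNF-DeltaARE replicate 1 with WT replicates 2 and 3, which points to a structure of the samples other than genotype. It was 0 for both p75-deleted comparisons. For the differences between cell types 100 splits were used, and 5 of 100 gave at least 4 genes (TNF-DeltaARE effect, highest other 92) and 5 of 100 at least 21 (p75 effect, highest other 893). Chance is not excluded for either, and splits that call many times the real count point to a structure of the samples.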

How the results depend on the processing

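Voom on recovered reads, scaling to equal totals, the GC correction, 1 gene per near-identical cluster, the terms for sex and macrophage transcripts, the fit of all libraries of a cell type against WT and the settings of the return count other than its threshold were chosen only after the data were seen. TMM, edgeR and DESeq2 (also for the return count and named genes) were not run, because the values are not counts. A return count in VIC could not be made, since 0 genes were called there. No named gene reversed its direction under rescaling, a replicate block, the GC correction or leaving out 1 library. The majority of calls turned in 1 case, p75-deleted against TNF-DeltaARE SF, from 740 up and 278 down to 449 up and 620 down at equal totals. Of counts of genes 157 values stayed within 1.5 times the main count and 81 did not, and of counts of lists 99 and 28. Of the named genes' values 642 kept their direction and side of the threshold, 132 kept the direction but lost the threshold, 10 gained it and 0 moved. These values pool all settings over 196 named genes (each counted per comparison), of which 149 were called and 47 were not. Leaving out 1 library gave 90 of the losses, so most of the named calls failed in at least 1 such fit. In TNF-DeltaARE against WT SF 21 named genes lost their call in this way. Where leaving out 1 library left 1 p75-deleted SF library, that library was assumed to vary like the other groups. Depth limits low genes, and recovery of 2-fold changes was low throughout. The cause of the moves below was not tested, except that a stricter threshold or fewer libraries leaves fewer calls by construction.

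In SF, TNF-DeltaARE against WT gave 93 genes, but 13 at an adjusted p of 0.01, 36 in the fit of all 17 libraries and 47 with voom. Without TNF-DeltaARE replicates 1, 2 and 3 the count was 17, 16 and 196, and without WT replicates 1, 2 and 3 it was 24, 34 and 39. p75-deleted against WT gave 359, but 43 with no filter, 42 at 0.01, 716 with all SF libraries in the fit, 186 with voom, 232 at equal totals and 2 with the sex term. Leaving out 1 library gave 32 (WT replicate 1) to 366 (p75-deleted replicate 3), with 35 without p75-deleted replicate 1 and 59 and 80 without WT replicates 2 and 3. p75-deleted against TNF-DeltaARE gave 1018, but 648 with no filter, 201 at 0.01 and 663 with only the libraries compared. Leaving out 1 library gave 356 (TNF-DeltaARE replicate 1) to 1121, with 431 without TNF-DeltaARE replicate 2 and 420 without p75-deleted replicate 1. With 1 gene per near-identical cluster, a test first made for a pattern that was then not weighed, 313 and 955 passed in the p75-deleted comparisons, and with the GC correction 344 (292 up, 52 down) and 941 (673 up, 268 down). The 10 genes shared by both genotypes became 0 at 0.01 and 32 at an adjusted p of 0.1. The 43 that returned became 90 at 0.1 and 20 with voom. Without TNF-DeltaARE replicates 1, 2 and 3 they were 11, 13 and 79, and without WT replicates 1, 2 and 3 they were 17, 15 and 16.

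In VIC, TNF-DeltaARE against WT called 0 genes in all settings but 1, with 0 to 3 when 1 library was left out (3 without TNF-DeltaARE replicate 1). p75-deleted against WT called 0, but 8 in the fit of all 17 libraries and 16 with the sex term, and 0 to 12 without 1 library (12 without WT replicate 2, 2 without WT replicate 3). p75-deleted against TNF-DeltaARE called 0, but 4 in the fit of all 17. WT VIC against SF gave 1801, but 992 at 0.01, and 1234 to 2004 without 1 library. The 4 genes of the TNF-DeltaARE effect became 0 with no filter, at 0.01 and with voom, 2 at 5 CPM and 8 with a pseudocount of 10. They ranged from 0 (without SF TNF-DeltaARE replicate 1 or 2, SF WT replicate 1 or 3, VIC TNF-DeltaARE replicate 2 or 3, or VIC WT replicate 2) to 6 (VIC WT replicate 3), with 1 without SF WT replicate 2. The 21 of the p75 effect became 3 with median-ratio rescaling or a pseudocount of 0.1, 7 with no filter, 0 at 0.01, 73 with a pseudocount of 10, 1 with voom, 4 at equal totals or with the sex term, and 8 with the GC correction. They ranged from 0 (without SF TNF-DeltaARE replicate 1, VIC TNF-DeltaARE replicate 2, or VIC p75-deleted replicate 1 or 2) to 149 (SF p75-deleted replicate 3). The count was 7 and 3 without SF TNF-DeltaARE replicates 2 and 3, 2 without SF p75-deleted replicate 1, 3 without any 1 SF WT library, 68 and 4 without VIC TNF-DeltaARE replicates 1 and 3 and 4 without VIC WT replicate 2.

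Of gene lists 0 passed with an estimated correlation and 0 with fry in the 3 SF comparisons, TNF-DeltaARE against WT VIC, p75-deleted against WT VIC and both differences of effects. In p75-deleted against TNF-DeltaARE VIC 1 list passed with each, and between WT cells 1 with an estimated correlation. Without 1 library the lists that passed numbered 10 to 16, 1 to 8 and 4 to 9 in the SF comparisons in the order above. For p75-deleted against WT it was 1 without p75-deleted replicate 3 or WT replicate 1 and 2 without WT replicate 3. In TNF-DeltaARE against WT VIC the range was 4 to 13 (10 without TNF-DeltaARE replicate 3, 13 without WT replicate 3). For the TNF-DeltaARE effect it was 5 (without VIC WT replicate 1) to 13, and for the p75 effect 2 (without SF p75-deleted replicate 3 or VIC TNF-DeltaARE replicate 3) to 10, with 3 without VIC p75-deleted replicate 2.

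Whether the labels' replicate numbers pair the samples is not settled. Correlations of same-numbered libraries ran from -0.539 to 0.361 within a cell type. Not every library correlated best with its own number, though some did, such as replicate 3 of p75-deleted and WT SF (0.145). Groups this small cannot exclude a pairing. With a replicate block the counts were 68 and 793 for the mutants against WT in SF, 753 for p75-deleted against TNF-DeltaARE SF, 0 in each VIC comparison, 1451 between WT cells, and 2 and 0 for the TNF-DeltaARE and p75 effects. With the replicate block 10 lists passed for p75-deleted against WT SF and 8 for TNF-DeltaARE against WT VIC, and no other list count moved by over 1.5 times.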

Other observations

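Some genes called in the authors' deposited tables but not by limma had libraries of 1 group far apart, and they are given here by library, chosen after their values were seen. The macrophage and leukocyte list did not pass between TNF-DeltaARE and WT SF, with 0 up and 0 down of 22, also adjusted over the list alone (median 0.13, camera adjusted p = 0.872). Without TNF-DeltaARE replicate 3 it ranked higher (adjusted p = 0.0012), and in 4 of the 6 fits without 1 library its direction was down. Single genes that the authors' deposited table lists higher in TNF-DeltaARE SF included the arginase Arg1 (6.14), Il1b (5.23), the neutrophil collagenase Mmp8 (4.28), the platelet factor Pf4 (3.81) and the chemokine Ccl6 (2.97). Per library of TNF-DeltaARE SF, Il1b read 217, 75 and 5, Arg1 185, 22 and 1, and Pf4 1035, 322 and 26, while WT SF read 0, 4 and 1 for Il1b, 0 in each library for Arg1 and 18, 55 and 23 for Pf4. The macrophage protein Cd5l, listed there at -5.43, read 63, 358 and 8 in WT SF and 0, 7 and 0 in TNF-DeltaARE. In VIC the authors' deposited table lists Rgs16, a regulator of G-protein signalling, at -5.21 in TNF-DeltaARE and -5.25 in p75-deleted cells. Rgs16 read 36, 48 and 6821 in the WT VIC libraries, 78, 56 and 50 in TNF-DeltaARE and 41, 96 and 42 in p75-deleted VIC. Rspo2, a Wnt agonist listed at -4.23 and -5.37, read 2, 198 and 4 in WT VIC, and the tendon gene Tnmd, listed at -4.54 and -3.73, read 4, 69 and 17. Both are among the SF genes held by VIC WT replicate 2. Gpnmb, a membrane glycoprotein listed at 2.62 in TNF-DeltaARE VIC, read 367, 2525 and 2599 there and 271, 285 and 335 in WT.

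Leukocyte and interferon transcripts varied between VIC libraries of 1 genotype. The mean log2 value of the macrophage list was 3.02, 6.32 and 3.04 in the WT libraries, 5.55, 2.19 and 2.12 in TNF-DeltaARE and 5.35, 6.40 and 7.18 in p75-deleted VIC. That of the interferon list was 4.00, 5.17 and 6.65, then 6.77, 5.81 and 4.34, then 7.65, 7.61 and 6.90. Xist read 105 in SF TNF-DeltaARE replicate 1, 58 and 102 in SF WT replicates 2 and 3, 331 in VIC TNF-DeltaARE replicate 2 and 180 and 110 in VIC WT replicates 2 and 3. The 5 p75-deleted libraries read 80 to 411 for the Y-linked Ddx3y and at most 2 for Xist.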
